A study of Elaeis guineensis with 12 samples.

How the data were processed

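RNA was measured in laser-captured staminodia and carpel of stage 3 florets from 3 mantled and 2 normal clonal oil palms, 12 libraries in all. Per the labels' protocols, captured cryosections gave total RNA that was treated with DNase and depleted of ribosomal RNA, and stranded libraries were made with the SMARTer Stranded kit and sequenced as paired ends of 2 lengths on HiSeq or MiSeq instruments. The labels do not say which library had which length or instrument, so neither could be checked as a batch. Per the submitters' processing notes the tools were CASAVA 1.8.2, Trim Galore, cutadapt, TopHat2 2.0.13 and HTSeq 0.6.1p1. The genome build, annotation version and strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may share features.

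The authors deposited whole-number read counts per feature, 1 table per library and not normalised, as the values show. Each table listed 100342 features. Going by the form of the IDs, 92649 of these carried a part number within 18394 gene models and 7693 stood for 1 model each. Read so, a long gene can contribute several features. No annotation was at hand to check this reading, on which the sums per gene model and the tests of parts rest. That neighbouring model numbers lie close together on a scaffold is likewise assumed. Reads that the counting assigned to no feature made up 46.9% to 50.5% of all rows, ambiguous reads 10.9% to 14.3% and multiply aligned reads 5.78% to 16.7%, and these rows were left out of library sizes and tests. Assigned counts made up 25.3% to 32.2%, or 2121145 to 8066978 per library, and 29244 features had no read in any library. Reads that align to several places are not assigned to a feature, so recent gene copies are undercounted. The sources used here name no molecular identifiers, so reads are not independent molecules.

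None of the feature IDs (0 of 100342) matched the 185249 symbols, locus tags and accessions of the reference gene table. The 31 gene lists fixed before the data were examined, which covered floral regulators and heat shock proteins among others, could therefore not be matched to any feature, and neither they nor their alternatives were run. For the same reason features are given by ID.

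Comparisons, tests, alternatives and the rule for named features were fixed before the data were examined. The palm was the replicate: libraries of 1 tissue from the same palm were summed, which joined normal replicates 1 and 2. Their counts differed by more than sampling noise, with a chi-square per degree of freedom of 7.00 in staminodia and 7.59 in carpel against 14.7 to 26.3 for libraries of different palms, over features with 20 or more reads. Mantled and normal palms were compared in each tissue with edgeR 4.0.16 (R 4.3.3): filterByExpr with its minimum count of 10, TMM factors, robust dispersions, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. Staminodia and carpel were compared in 1 fit of all palm by tissue sums with palm as a block, since the labels give both tissues the same palm IDs, and the interaction came from that fit. In it the prior degrees of freedom that edgeR estimated had an infinite median over features. Most features thus took the trended spread with no spread of their own, and their p-values are less cautious where they vary more than the trend. In the staminodia and carpel fits the median prior degrees of freedom were 16.1 and 12.0. Levels are TMM-normalised CPM of the palm sums with their SD over palms. Each SE was worked back from the test, as the absolute log2 value divided by the square root of the quasi-likelihood F statistic. The groups hold 2 or 3 palms, so p-values of the staminodia and carpel fits rest on few palms and on spread borrowed across features. In the fit of both tissues most p-values rest on the trended spread of all features and not on a feature's own spread among palms.

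The rule for named features took, without gene names, up to 2 IDs higher and 2 lower per comparison: those of smallest p where fewer than 10 features were called, and otherwise the largest log2 fold changes among called features with a mean log2 CPM of at least 1 and the same direction in every palm. The steps were tested on simulated counts with the real means, library sizes and dispersions and 200 features changed by 2, 4, 8 or 16 times. Each feature had the same mean in all samples apart from these changes, so no palm or tissue effects were simulated. The false calls below therefore hold for such counts and do not vouch for the real calls. In the staminodia comparison (22788 features) 4%, 16%, 38% and 46% of these were recovered with 2 false calls among 54, and in the carpel comparison (27458 features) 0%, 14%, 36% and 46% with 2 among 50. In the 29923 features of the within-palm fit, recovery was 4%, 22%, 18% and 38% for tissues in normal palms, 6%, 20%, 34% and 54% in mantled palms and 2%, 12%, 18% and 50% for the interaction. All recovered features had the right sign. A change of 4 times or less would thus be missed in most features.

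Alternatives fixed in advance were median-ratio and upper-quartile factors, no filter, a filter of at least 1 CPM in 3 samples, DESeq2 1.42.0, edgeR without robust estimates, limma voom (limma 3.58.1), each library as a replicate, each replicate left out, all 4 groups in 1 fit and no replicate block. Alternatives chosen after seeing the data were sums over the parts of each gene model, library-level fits with the library number as a block, and an adjusted p of 0.10. Use of model parts was tested with edgeR's diffSpliceDGE and Simes p-values.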

Results

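The libraries measured RNA in florets of clonal oil palms, Elaeis guineensis, at stage 3 of floral development. Mantled palms are a somaclonal variant of tissue culture in which the staminodia, the sterile male organs of the female flower, develop as carpel-like pseudocarpels. Staminodia, the pseudocarpel initials of mantled flowers, and carpel, the female organ beside them, were cut out of frozen sections by laser capture and sequenced separately. Each of the 4 groups, mantled and normal by staminodia and carpel, held 3 libraries. Mantled libraries came from 3 palms and normal libraries from 2 palms, since normal replicates 1 and 2 were taken from parts of 1 inflorescence of normal palm 1 and replicate 3 from normal palm 2. Levels are therefore means over palms, in TMM-normalised CPM (read counts scaled by library size). Counts assigned to features ran from 2121145 in mantled carpel replicate 3 to 8066978 in mantled carpel replicate 2, with a median of 3232100 over the 12 libraries. Features with at least 1 read numbered from 25523 in normal carpel replicate 3 to 45987 in normal staminodia replicate 1, of 100342 listed. The files do not pair feature IDs with gene names, so features are given by ID, up to 2 per direction.

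The study's central question was how staminodia of mantled flowers differ from those of normal flowers. A feature on scaffold p5_sc00322, maker-p5_sc00322-snap-gene-9.52-mRNA-1:cds, was lower in mantled staminodia, at 89.4 CPM ± 31.4 (SD, n = 3 palms) against 963 ± 123 (SD, n = 2 palms) in normal staminodia. Feature maker-p5_sc00001-augustus-gene-87.59-mRNA-1:cds was also lower, at 137 CPM ± 59.4 (SD, n = 3) against 962 ± 257 (SD, n = 2). The 1 feature that was higher in mantled staminodia, maker-p5_sc00219-augustus-gene-5.38-mRNA-1:cds, reached 89.4 CPM ± 29.5 (SD, n = 3) against 8.40 ± 0.383 (SD, n = 2). In all, 9 of 22788 tested features passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1 higher and 8 lower in mantled staminodia. The log2 fold changes of the named features were -3.38 (SE 0.322, adjusted p = 5.14e-05), -2.75 (SE 0.331, adjusted p = 0.00106) and 3.44 (SE 0.518, adjusted p = 0.0132) in the order given. In 4 of the 9 features normal palm 1 exceeded normal palm 2 by 2 times or more. Of these 4, 1 had 0 reads in every mantled staminodia library and was at least 175-fold lower there, taking 3 counts over the group as the floor, or at least 218-fold against normal palm 1 alone and 25.1-fold against normal palm 2 alone.

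Unadjusted p-values under 0.05 were found for 811 features where 1139 would be expected without any difference. The number of calls was 0 without mantled replicate 1, 2 without mantled replicate 2, 4 without mantled replicate 3, 64 without normal replicate 3 and 82 without the pair of normal replicates 1 and 2. The balance of directions turned with the normal palm that was kept, with 4 higher and 60 lower in mantled staminodia without normal replicate 3 and 54 higher and 28 lower without the pair. Over 17 alternatives the adjusted p of the p5_sc00322 feature (maker-p5_sc00322-snap-gene-9.52-mRNA-1:cds) ran from 2.82e-27 to 0.0599, the highest without mantled replicate 1, where its log2 fold change was -3.13. The call of maker-p5_sc00001-augustus-gene-87.59-mRNA-1:cds was lost without mantled replicate 1 (-2.56) or 2 (-2.59), and that of maker-p5_sc00219-augustus-gene-5.38-mRNA-1:cds without mantled replicate 1 (3.23), 2 (3.66) or 3 (3.41). Their adjusted p reached 0.714 in edgeR in both cases, from lowest values of 1.63e-21 and 2.06e-07.

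**Figure D1:**
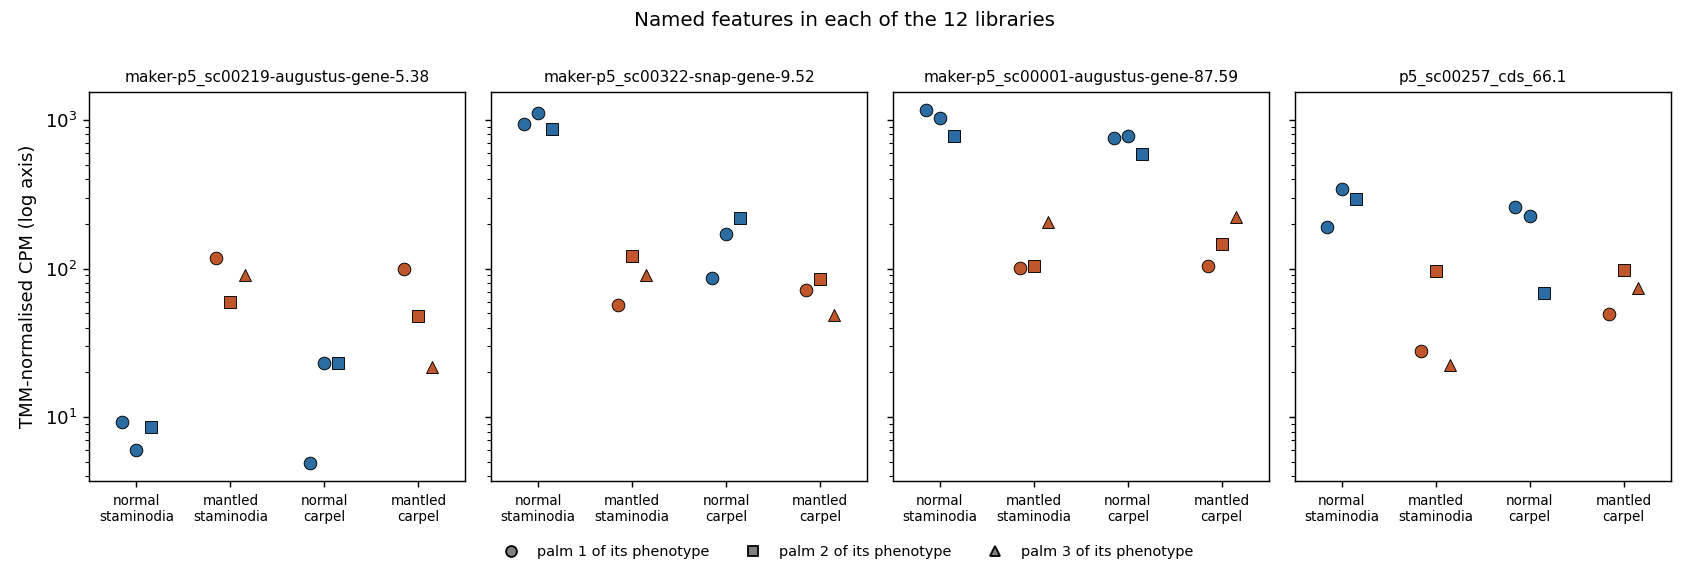
TMM-normalised CPM (log axis) of 4 named features in each of the 12 libraries, by phenotype and tissue. Each point is 1 library and its shape marks the palm within its phenotype, so the pair of normal circles in each group comes from 1 palm; normal staminodia lie at 871 CPM or above in the p5_sc00322 panel and mantled staminodia at 121 CPM or below.

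The same comparison in carpel asked whether mantled palms also differ in the neighbouring female organ. The feature with the smallest p had lower values in mantled palms, as in staminodia. Feature maker-p5_sc00001-augustus-gene-87.59-mRNA-1:cds stood at 157 CPM ± 59.6 (SD, n = 3) in mantled carpel against 703 ± 162 (SD, n = 2) in normal carpel, a log2 fold change of -2.13 (SE 0.316) with an adjusted p of 0.18 in edgeR. Feature p5_sc00008_cds_513.1 stood at 3.81 CPM ± 2.04 (SD, n = 3) against 52.5 ± 54.7 (SD, n = 2), with a normal spread as wide as the difference. The features with the smallest p among those with higher values in mantled carpel were maker-p5_sc00079-augustus-gene-29.45-mRNA-1:cds, at 60.2 CPM ± 42.5 (SD, n = 3) against 10.5 ± 4.82 (SD, n = 2), and snap_masked-p5_sc10954-processed-gene-0.2-mRNA-1:cds, at 81.8 ± 35.0 against 25.9 ± 7.34. None of 27458 tested features passed the threshold in edgeR, 824 had an unadjusted p under 0.05 where 1373 would be expected, and DESeq2 called 3 and limma voom 56. Without mantled replicate 3 edgeR called 3 features, without normal replicate 3 it called 31 (3 higher, 28 lower), and without the pair of normal replicates 1 and 2 it called 296 (255 higher, 41 lower). The call of maker-p5_sc00001-augustus-gene-87.59-mRNA-1:cds was gained in each of these 3 settings, with log2 fold changes of -2.48, -2.36 and -1.89, and with all palms in DESeq2 (-2.12), in limma voom (-2.31), without a filter (-2.16) and with all 4 groups in 1 fit (-2.14), over an adjusted p range of 6.69e-10 to 1 in 17 alternatives. Feature p5_sc00008_cds_513.1 was called without a filter (-3.84), in limma voom (-3.88) and without normal replicate 3 (-4.63), and maker-p5_sc00079-augustus-gene-29.45-mRNA-1:cds without a filter (2.48). The log2 fold change of the former was -3.8 with all palms and -1.86 without the pair of normal replicates 1 and 2.

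Of the 9 features called in staminodia, 8 were also tested in carpel. All 8 had the same direction there, and 7 of them had an unadjusted p under 0.05 in the carpel fit, while 0 passed the adjusted threshold. Across 21359 features tested in both tissues, the mantled over normal log2 fold changes had a Pearson r of 0.236 and a Spearman rho of 0.227, and 58.7% shared a sign. Features are not independent replicates, and both tissues came from the same palms. Regrouping the 5 palms in the 9 other ways into 3 and 2 gave a Pearson r of 0.132 to 0.352, and 5 of these 9 were at least as high as that of the real grouping. Without normal replicate 3 the Pearson r was 0.408, and with each library as a replicate it was 0.326.

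In normal palms, staminodia and carpel were compared within each palm to show what sets the organs apart in an unaffected flower. Feature p5_sc00011_cds_431.2 was higher in staminodia, at 65.7 CPM ± 24.4 (SD, n = 2 palms) against 8.60 ± 11.6 (SD, n = 2) in carpel, and maker-p5_sc00153-augustus-gene-16.17-mRNA-1:cds was at 51.4 ± 9.91 against 12.6 ± 16.7. Higher in carpel were maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds, at 14.6 CPM ± 13.4 (SD, n = 2) against 1.66 ± 2.34 in staminodia, and p5_sc00042_cds_38.1, at 47.3 ± 3.40 against 14.2 ± 18.1. With palm as a block, edgeR's quasi-likelihood test called 56 of 29923 features, 38 higher in staminodia and 18 higher in carpel. Unadjusted p-values under 0.05 were found for 1294 features where 1496 would be expected without any difference. The named log2 differences, staminodia over carpel, were 3.57 (SE 0.564, adjusted p = 2.39e-06), 2.77 (SE 0.661, adjusted p = 0.0227), -3.29 (SE 0.763, adjusted p = 0.0152) and -2.40 (SE 0.598, adjusted p = 0.0395).

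These calls rested on the pairing of tissues by palm: with no replicate block, 1 feature was called. The count was 27 without mantled replicate 2, 124 without normal replicate 1, 35 without normal replicate 2, 1 without normal replicate 3 and 975 without the pair of normal replicates 1 and 2, where 1 normal palm is left and is assumed to vary like the mantled palms. All 4 named calls were lost without normal replicate 3, with log2 differences of 2.30 for p5_sc00011_cds_431.2, 0.866 for maker-p5_sc00153-augustus-gene-16.17-mRNA-1:cds, -2.85 for maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds and -0.883 for p5_sc00042_cds_38.1. The calls of the last 2 were also lost without mantled replicate 1 (-3.37 and -2.43), mantled replicate 2 (-3.33 and -2.43) or normal replicate 2 (-2.69 and -2.37), and that of the p5_sc00153 feature (maker-p5_sc00153-augustus-gene-16.17-mRNA-1:cds) without mantled replicate 2 (2.80). Without normal replicate 1, maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds stood at -5.35 and p5_sc00042_cds_38.1 at -2.55. Without the pair of normal replicates 1 and 2 the fitted differences of the 4 features, in the same order, were 6.83, 6.16, -7.23 and -4.99. All 4 rest on few reads: the normal carpel library left held 1 and 2 reads of the first 2, and the normal staminodia library left 0 and 3 of the last 2. All 4 calls were also lost with limma voom, at 2.85, 1.51, -3.25 and -1.31, and with no replicate block, at 2.87, 2.00, -2.90 and -1.70, and DESeq2 gave no adjusted p for them. Those of maker-p5_sc00153-augustus-gene-16.17-mRNA-1:cds and p5_sc00042_cds_38.1 were lost with each library as a replicate (2.02 and -1.81), with the library number as the block (2.26 and -1.83) and without a filter (2.86 and -2.49). With sums per gene model only that of p5_sc00011_cds_431.2 was kept, and the others stood at 2.71, -3.27 and -2.35. The sums leave the counts of maker-p5_sc00153-augustus-gene-16.17-mRNA-1:cds and maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds unchanged. Their calls were thus lost through the refit of all features and not through their own counts.

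In mantled palms, where the staminodia take on a carpel-like form, the same comparison was made over 3 palms. Feature p5_sc00059_cds_264.1 was higher in staminodia, at 121 CPM ± 33.2 (SD, n = 3 palms) against 46.3 ± 19.2 in carpel, and p5_sc00102_cds_10.1 was at 167 ± 58.3 against 77.2 ± 39.8. Higher in carpel were p5_sc00012_cds_152.1, at 18.5 CPM ± 12.2 (SD, n = 3) against 0.743 ± 0.903 in staminodia, and maker-p5_sc00060-augustus-gene-4.47-mRNA-1:cds, at 54.8 ± 36.7 against 7.22 ± 9.92. edgeR called 50 of 29923 features, 18 higher in staminodia and 32 higher in carpel, and the split was 24 and 26 with median-ratio size factors. The balance turned with the tool and the counting unit, to 52 and 34 in DESeq2, 34 and 23 in limma voom and 14 and 11 with sums per gene model, so no balance of directions is read from the 50. The named log2 differences were 1.42 (SE 0.283, adjusted p = 0.000932), 1.21 (SE 0.238, adjusted p = 0.000766), -4.70 (SE 1.02, adjusted p = 0.00411) and -3.38 (SE 0.551, adjusted p = 3.91e-06). Over all tested features, 1107 had an unadjusted p under 0.05 in edgeR where 1496 would be expected without any difference.

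With no replicate block 0 features were called in mantled palms, with sums per gene model 25, with each library as a replicate 9, without mantled replicate 2 25, and without mantled replicate 3 10. The 4 named differences with no replicate block stood at 1.39, 1.11, -4.61 and -2.95 in the order given above. The call of p5_sc00059_cds_264.1 was lost without mantled replicate 3 (0.905), that of p5_sc00102_cds_10.1 without mantled replicate 1 (1.17) or 3 (1.03), that of p5_sc00012_cds_152.1 without mantled replicate 2 (-4.05) or 3 (-3.88), and that of maker-p5_sc00060-augustus-gene-4.47-mRNA-1:cds without mantled replicate 2 (-2.31) or normal replicate 1 (-3.40). Without mantled replicate 1 the last 2 features stood at -6.48 and -4.38. Mantled staminodia replicate 2 held 0 reads of both. With each library as a replicate all 4 calls were lost while the log2 differences stood at 1.43, 1.22, -4.61 and -3.31, and with the library number as the block those of p5_sc00059_cds_264.1 (1.43) and p5_sc00102_cds_10.1 (1.22) were called. With limma voom all but that of p5_sc00102_cds_10.1 were lost, at 1.20, -4.67 and -3.51. With sums per gene model those of p5_sc00012_cds_152.1 (-4.74) and maker-p5_sc00060-augustus-gene-4.47-mRNA-1:cds (-3.33) were lost. DESeq2 gave no adjusted p for these 2. The sums leave the counts of maker-p5_sc00060-augustus-gene-4.47-mRNA-1:cds unchanged, and its adjusted p in edgeR was 0.466 there.

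The tissue differences of normal and mantled palms overlapped in part. Of the features higher in staminodia, 4 were called in both phenotypes where 0.0229 would be expected from independent lists, and of those higher in carpel, 4 were called in both where 0.0192 would be expected (one-sided Fisher's exact p = 6.68e-09 and 3.26e-09), while 0 were called in opposite directions. These p-values count each feature as independent, whereas 3 of the 4 shared carpel features came from gene models within 5 model numbers of each other on scaffold p5_sc00001. Features called in normal palms had the same direction in mantled palms in 35 of 38 cases for staminodia and 15 of 18 for carpel. Their median log2 difference was 1.22 in normal and 0.353 in mantled palms for the former, and -1.56 and -0.429 for the latter. Features called in mantled palms went the same way in normal palms in 17 of 18 and 29 of 32 cases, with medians of 0.944 in mantled and 0.491 in normal palms for those higher in staminodia, and -1.29 and -0.703 for those higher in carpel. Each list was picked by its own phenotype, which alone lowers its median in the other, and only the interaction tests the difference itself.

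**Figure D2:**
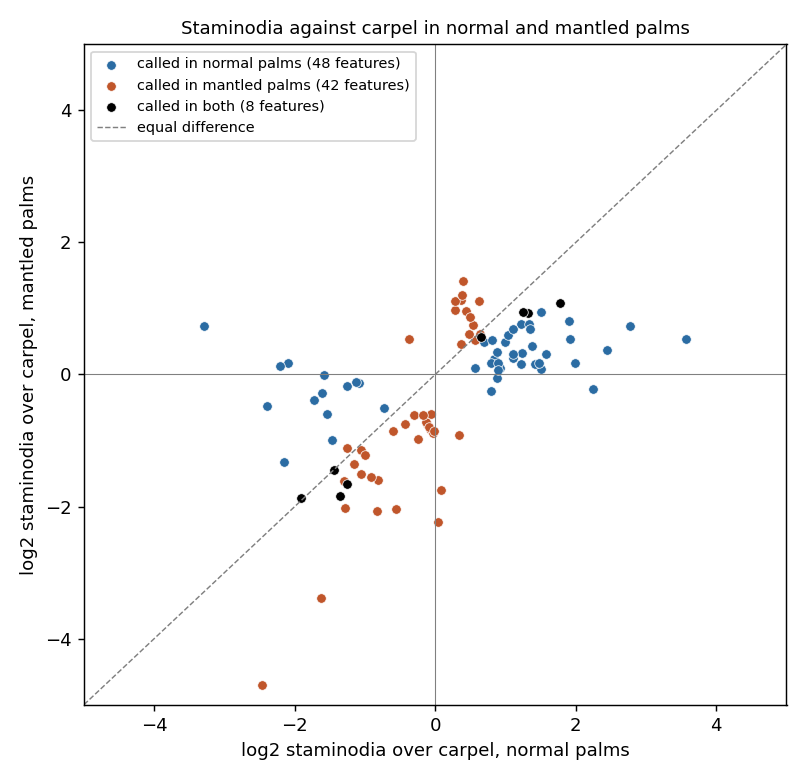
Log2 difference of staminodia over carpel in normal palms (x axis) and mantled palms (y axis) for each feature called in either, coloured by where it was called, with a dashed line of equal difference. The 8 features called in both phenotypes lie on the same side of 0 on both axes, and features called in 1 phenotype lie nearer to 0 on the other's axis in most cases.

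The interaction asked directly whether the staminodia over carpel difference depended on the phenotype. The p5_sc00322 feature, maker-p5_sc00322-snap-gene-9.52-mRNA-1:cds, was higher in staminodia than in carpel in normal palms (963 CPM ± 123 against 181 ± 51.3, SD, n = 2 palms) and stood at 89.4 ± 31.4 against 68.2 ± 18.6 (SD, n = 3 palms) in mantled palms. Its log2 difference was 2.44 (SE 0.227) in normal and 0.36 (SE 0.183) in mantled palms, an interaction of -2.08 (SE 0.286, adjusted p = 1.15e-08 in edgeR). Feature p5_sc00257_cds_66.1 stood at 281 CPM ± 18 in normal staminodia, 162 ± 132 in normal carpel, 48.6 ± 40.5 in mantled staminodia and 73.7 ± 24.8 in mantled carpel, an interaction of -1.89 (SE 0.384, adjusted p = 0.0129). The 1 feature with a positive interaction, maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds, stood at 1.66 CPM ± 2.34 in normal and 49.1 ± 20.8 in mantled staminodia, against 14.6 ± 13.4 and 29.9 ± 15.8 in carpel, an interaction of 4.03 (SE 0.914, adjusted p = 0.0484). In all, 7 of 29923 features passed the threshold, 1 positive and 6 negative, or 2 and 3 with median-ratio size factors and 4 and 4 in DESeq2, against a median over all features of -0.257. An unadjusted p under 0.05 was found in edgeR for 916 features where 1496 would be expected without any difference.

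With no replicate block the interaction called 0 features, while the 3 named interactions stood at -2.02, -1.40 and 3.61 in the order given above. With each library as a replicate it also called 0. The count was 4, 3 and 1 without mantled replicates 1, 2 and 3, 13, 2 and 2 without normal replicates 1, 2 and 3, and 553 without the pair of normal replicates 1 and 2. The p5_sc00322 feature (maker-p5_sc00322-snap-gene-9.52-mRNA-1:cds) was called in each of these left-out settings, with interactions of -2.50 to -1.67. Without normal replicate 1 the interactions of p5_sc00257_cds_66.1 and maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds were -2.16 and 6.09. The call of p5_sc00257_cds_66.1 was lost without mantled replicate 3 (-1.44), normal replicate 2 (-1.60) or normal replicate 3 (-0.903), and that of maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds without mantled replicates 1 (4.46), 2 (4.62) or 3 (3.31) or normal replicates 2 (3.44) or 3 (3.58). Without the pair of normal replicates 1 and 2 these features were called at -2.95 and 7.95, the latter against 0 reads in the normal staminodia library left. Both calls were lost with limma voom (-0.946 and 3.75), without a filter (-1.91 and 4.09) and with sums per gene model (-1.83 and 4.03), and DESeq2 gave no adjusted p for them. The positive interaction was also lost at 1 CPM in 3 samples (4.05) and without robust estimates (4.03), and so was not called in 13 of 17 alternatives. With each library as a replicate and palm as the block the 3 named interactions were -2.25, -1.52 and 3.92, none of them called, and with the library number as the block that of maker-p5_sc00322-snap-gene-9.52-mRNA-1:cds was called at -2.30. Its adjusted p in edgeR was 0.0682 and 0.0343 in these fits, within a range of 3.55e-11 to 1 over 18 alternatives.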

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

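The tests in this part were all fixed before their results were seen. Of the features named for the interaction, 3 differed between staminodia and carpel in their mantled over normal fold change: maker-p5_sc00011-augustus-gene-15.48-mRNA-1:cds by 4.03, maker-p5_sc00322-snap-gene-9.52-mRNA-1:cds by -2.08 and p5_sc00257_cds_66.1 by -1.89 on the log2 scale, each past the adjusted threshold of edgeR's interaction test.

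The interaction calls were weighed against the influence of a single palm. In 1 of the 7 called features the contrast lost over 50% of its size when some single palm was left out, namely p5_sc00257_cds_66.1, which went from -1.89 to -0.903 without normal palm 2. The other 6 kept their direction and more than that size without any 1 palm. Feature p5_sc00246_cds_36.1 (-1.15) stood at -1.45 without normal palm 2 and at -0.865 without normal palm 1. A further 3 of the 6 moved by over 1.5 times from their value with all palms when a normal palm was left out. These went from -3.03 to -1.77, from -2.53 to -1.33 and from 4.03 to 3.58 without normal palm 2, and to -6.31, -3.86 and 7.95 without normal palm 1, so the size of their interaction rests on single normal palms. Other tested parts of the same models went the same way in 66.7% of 3 cases, too few for an exact binomial test (smallest p 0.125), and of the 10 groupings of the 5 palms the real one called 7 features and the highest other 2, and 10 groupings are too few for a share under 0.05, so a difference tied to phenotype in the p5_sc00322 feature stays open beside chance among few palms.

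The 9 features called in staminodia were weighed against depth and palm background. The summed normal palm 1 held 7516856 counts, and after thinning to 2777658 the median absolute log2 fold change of the 9 features was 0.982 of its value, with all 9 still called. Thinning leaves the expected fold changes as they were, so this ratio decides nothing about depth. All 9 were still called at the lower depth, which argues against the extra counts of normal palm 1 as what made these calls. Mantled palm 1 carries an ID of another series than the other palms. Without it the median went from 3.44 to 3.47, a ratio of 1.01, and all 9 directions held, so the fold changes were as large in the other mantled palms. The directions were all but fixed, since mantled and normal libraries did not overlap in any of the 9. The 9 were also picked with that palm included, so the test gives no verdict on its background. With 2 palms against 2, 0 of the 9 calls remained. A single other part of a called model could be tested and went the same way (100% of 1, smallest possible exact p of 0.5). The real grouping called 9 features against 6 for the highest of the other 9 groupings of palms. As 10 groupings are too few for a share under 0.05, chance and differences among palms stay open.

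Other groupings were also run for further counts. In carpel the real grouping called 0 features, so all 10 groupings gave at least as many by construction, which decides nothing, and the highest other gave 2. For staminodia against carpel in mantled palms, the real labels called 50 features and the highest of the other 3 ways of labelling tissues within palms gave 2, and 4 ways are too few for a share under 0.05.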

How the results depend on the processing

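Sums per gene model, the library-number block and the adjusted p of 0.10 were chosen after seeing the data. Gene lists and their alternatives were not run, as no ID had a name. Of 308 values for the named features, 0 changed direction, 217 kept their side of the threshold, 80 were no longer called and 11 became called, and DESeq2 gave no adjusted p for 9 more.

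Counts of calls are given in the order staminodia, carpel, tissues in normal palms, tissues in mantled palms and interaction, against 9, 0, 56, 50 and 7. Without a filter they were 56, 23, 25, 32 and 1. DESeq2 gave 45, 3, 62, 86 and 8, and limma voom 77, 56, 149, 57 and 31. Without robust estimates staminodia gave 14. With all 4 groups in 1 fit carpel gave 1. With at least 1 CPM in 3 samples the interaction gave 2. Each library as a replicate gave 10, 0, 51, 9 and 0. Sums per gene model gave 3, 0, 25, 25 and 2, with fewer features tested and the spread and scaling fitted anew. Features that stand for 1 model each keep their own counts in these sums, yet some of their calls were lost. With no replicate block, the tissue counts and the interaction were 1, 0 and 0. Differences between palms then enter the spread by construction, and this was not separated from other changes in the fit. The replicate block by library number gave 67, 17 and 5. Except where the construction shows it, the cause was not tested.

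Leaving out replicates gave 0 to 82, 0 to 296, 1 to 975, 10 to 70 and 1 to 553 calls. The highest in each came without the pair of normal replicates 1 and 2, which leaves 1 normal palm whose spread is assumed to match the mantled palms. The correlation of fold changes between tissues, 0.236, ranged from 0.18 to 0.408 with replicates left out and was 0.326 with each library as a replicate. Median-ratio and upper-quartile factors, and an adjusted p of 0.10, kept all 5 counts within 1.5 times.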

Other observations

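In this part only the tests of neighbouring gene models were chosen after the result was seen. Of the 4 features higher in carpel in both phenotypes, 3 came from gene models within 5 model numbers of each other on scaffold p5_sc00001. In 10000 random draws of 4 tested features 0 had as many neighbouring pairs (permutation p = 1e-04, the smallest these draws can give), but the window and the list were set once the neighbours had been seen, so this value decides nothing about placement by chance. All 8 other tested parts of these models (100%) were higher in carpel in normal palms (one-sided exact binomial p = 0.00391) and all 8 in mantled palms. The other parts thus went the same way as the called ones. They come from few models and the same palms and are not independent, so this p-value overstates the weight against single parts counted at random. Parts of other models close by were higher in carpel in 9 of 10 cases in normal palms and 5 of 10 in mantled palms. The even split that the binomial test assumes was therefore not seen nearby in normal palms. Beside placement by chance, a candidate explanation is a run of related or jointly regulated genes marking carpel in normal and mantled flowers, and 1 transcript split over several models stays open, since neither sequence nor names were used here.

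It was asked whether mantled staminodia were closer to carpel. The covariance across features of the within-palm staminodia over carpel differences averaged 0.0981 over pairs of mantled palms and was 0.109 for the pair of normal palms, a difference of -0.0109. As low a value came from 5 of the 10 groupings of palms, the real one included, and the lowest other was -0.0746, so the data do not separate the phenotypes by this measure. The matching correlations ran from -4.88e-05 to 0.0532 over all pairs of palms and were 0.0429 for the normal pair. The measured tissue differences over all features were thus barely correlated between any 2 palms, also within a phenotype. Noise in the counts lowers such correlations and was not corrected for, so how much of the tissue difference the palms share stays open. Features called in normal palms went the same way in mantled palms in 89.3% of 56 cases (one-sided exact binomial p = 5.09e-10), and features called in mantled palms went the same way in normal palms in 92% of 50 cases (one-sided exact binomial p = 2.23e-10). Most called features thus kept their direction in the other phenotype. The binomial p-values count each feature as an independent trial, whereas all features were measured in the same 5 palms and in 1 fit. They therefore do not measure the spread among palms, and features of 1 model are not independent either.

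The fold changes shared by staminodia and carpel may come from the palms and not the phenotype, since 5 of the 9 other groupings of palms gave a correlation at least as high as 0.236 and the highest gave 0.352. The use of parts within gene models showed 0 models past an adjusted p of 0.05 by edgeR's Simes test between mantled and normal palms in staminodia (4405 models, 27 with an unadjusted p under 0.05) and 0 in carpel (5512 models, 41 with an unadjusted p under 0.05), and the same palms allowed few calls for single features, so no bound on part usage follows.

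Staminodia and carpel libraries of the same number correlated more with each other than with libraries of other palms by 0.0839, 0.13, 0.13 and 0.0744 in mantled pairs 1 and 2 and normal pairs 1 and 2, and by -0.0114 in mantled pair 3 and -0.04 in normal pair 3 (log CPM over 31757 features). After thinning all libraries to 2121145 counts the values were 0.0699, 0.116, 0.115, 0.0664, -0.00664 and -0.0368. A split into 3 close and 3 other pairs, as asked in advance, left a gap of 0.00349 after thinning, and normal pair 2 falls with the close pairs, so that test of depth decides nothing.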
